A study of Mus musculus with 32 samples.

How the data were processed

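Total RNA of 32 mouse livers was extracted with Trizol and RNeasy columns and checked on a Bioanalyzer, per the labels' protocols, and hybridised with one dye (Cy3) to Agilent arrays of 62976 spots. Per the file headers, the slides were read and quantified with Feature Extraction 10.7.3.1, and the deposited scanner files hold spot values as linear intensity, background-subtracted by that software in the processed signal. Per the file headers, 3671 spots are controls, leaving 59305 spots of 55681 probes. The deposited table of processed values is on the log2 scale, from the values; per the submitters' processing notes limma was used, with no version given. Its column medians run from 6.50 to 6.52 in the baseline set and from 6.99 to 7.00 in the set after hepatectomy. Scale and direction follow from the scanner values (log2, higher is more), while the centring of each set stays unknown.

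Groups were taken from the labels and from the sample records in the scanner files. Columns of the processed table were set against the scanner arrays by rank correlation over 59305 spots. All 32 columns had their best match (r 0.994 to 0.998) in an array of the same replicate number, but 16 matched another group, MCD diet being exchanged with standard diet with agonist, before and after hepatectomy alike. Against their own arrays these 16 reached 0.871 to 0.941. The table therefore served only as an alternative, once as deposited and once with each column placed at the array it matches. Against the plan it was not used for the hepatectomy contrasts, because the medians of its 2 sets differ.

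The values tested were log2 of the processed signal minus each array's 75th percentile. Spots marked as non-uniform or population outliers were left out (5010 spots, 0.264%), saturated spots were kept and repeated spots of a probe were averaged. A probe entered if it was well above background on all 4 arrays of at least 1 group, which kept 30118 probes. A gene is one symbol, measured by its probe with the highest mean; 5888 of 21691 genes had several tested probes, and probes that disagree are mentioned with the gene. A gene not well above background on any array of one group has only a bound, given as at least N-fold: the bright group's mean against the dim group's mean of, per array, the higher of the dim probe's own value and the lowest value among probes well above background.

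Probe names came from the files. Symbols were updated through a reference table of assembly GRCm38.p6, used for names only: 31161 spots matched by accession, 3502 by symbol and 321 by synonym, and 24321 kept the file's name. Of the tested genes 15203 have a matched name and 6488 the file's name. Coordinates are probe positions on mm9 as the files give them, and whether a probe lies in an exon or UTR was not looked up.

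Comparisons were contrasts of one limma fit over the 8 groups (R 4.3.3, limma 3.58.1) with empirical Bayes moderation and Benjamini-Hochberg adjusted p under 0.05; "rose" and "fell" are used for genes that passed. Gene lists, 24 of pathways and 14 of cell types, were tested with camera at a preset correlation of 0.01, with an estimated correlation beside it, and adjusted over the 38 lists of a comparison. Some lists share members, up to 7 between amino acid catabolism and periportal markers. A list score is the mean of its members after centring each gene. Lists, tests, the alternatives named in the next paragraph and the rule for named genes were fixed before the data were examined. That rule names the 8 largest rises and 8 largest falls among called genes whose arrays do not overlap between groups (for interactions without this condition), up to 4 members of a described list with the smallest adjusted p, and a fixed set of focal genes such as Glp1r, Scd1 and Mki67; unnamed probes and clone symbols are left out, and not every gene that the rule allows is printed. Mat2a outside its list was added after its values were seen.

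In 1 simulated draw per comparison with 200 changed genes, limma called 19.4% of 2-fold and 80.3% of 4-fold changes for the agonist on standard diet after hepatectomy, 13.4% and 80.3% for the agonist on MCD diet after hepatectomy, and 17.9% and 77.3% for the diet at baseline. False calls numbered 1, 0 and 7, with 0 wrong signs. Alternatives were normexp background correction with offset 50, median scaling, quantile normalization, no filter on dim probes, the mean over probes, outlier spots kept, only the groups compared, the replicate number as a block, and each array left out in turn. The 4 slides were read with 2 scanners in 2 sessions, and a slide block could not be fitted for contrasts between slides, so fits to the groups compared alone served as the alternative within a slide.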

Results

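Gene expression was measured in livers of male C57/BL6 mice with 32 one-colour oligonucleotide arrays, one per liver. The 8 groups of 4 livers crossed a standard or a methionine-choline deficient (MCD) diet, which makes the liver fatty and inflamed, with or without an agonist of both the GLP-1 and the glucagon receptor, at baseline or 2 weeks after removal of 70% of the liver. The agonist was given at 4.4 mg/kg/day for 2 weeks, and in the hepatectomy groups diet and agonist went on until sampling, so livers before and after hepatectomy also differ in the length of diet and treatment. Between 43.1% and 69.1% of probes were well above background per array (median 52.6%), at most 2 spots were saturated, and 21691 genes entered the tests. The number of arrays limits the precision. Values below are log2 changes ± SE from limma, n = 4 livers per group, unless given as at least N-fold for genes that were not well above background on any array of one group.

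The arrays lay on 4 slides of 2 groups each, with each group filling 1 row of its slide. Both diet contrasts at baseline and both agonist contrasts after hepatectomy fall within a slide, while the agonist at baseline, the diet after hepatectomy and hepatectomy itself run across slides and cannot be told apart from a slide effect. The contrasts within a slide all set row 2 against row 1 and cannot be told apart from a row effect. The diet by agonist interactions cancel an additive slide effect. Groups follow the sample records of the scanner files. In the submitters' processed table, 16 of 32 columns match arrays of another group better than their own, so that table was not used for the main values. Of 142 list calls, 11 held with an estimated correlation: female-biased genes in 5 comparisons, adipocyte markers in 3, growth factors in 2 and the integrated stress response in 1. No called gene or list below changed direction under median or quantile scaling. Mup genes and the Cyp2b, Cyp3a and Cyp4a families share sequence, so single paralogs within them are uncertain. Glp1r and Gcgr, the agonist's receptors, passed in none of the 11 comparisons, the lowest adjusted p for Glp1r being 0.0518 with a log2 change of 1.39 ± 0.48 under agonist on MCD diet.

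The MCD diet at baseline, without agonist, shifted sex-biased liver genes from a male towards a female pattern. Sult1e1, an estrogen sulfotransferase (mm9 chromosome 5, 88005187 to 88005246), rose by 9.10 ± 1.43 (adjusted p = 4.61e-05). The female-predominant P450 genes Cyp3a44 and Cyp2b13 were at least 756-fold (adjusted p = 1.29e-11) and at least 75.1-fold higher (adjusted p = 5.33e-16). Among the falls, the fatty acid hydroxylases Cyp4a12a and Cyp4a12b changed by -6.06 ± 0.90 (adjusted p = 2.64e-05) and -5.27 ± 0.86, and the elongase Elovl3 fell 64.2-fold. Further large rises were Cyp2a22 (63.8-fold), Nupr1 (6.03 ± 0.61), Stap1 (at least 43.9-fold) and Slc22a27 (at least 40.2-fold), and further large falls Serpina4-ps1 (-10.40 ± 2.01), Hnf4aos (-6.24 ± 0.73), Pax2 (-5.97 ± 1.08), Obp2a (at least 14.1-fold) and Rd3 (-5.11 ± 0.56). Of the 14 measured female-biased genes, 9 rose, 0 fell and 5 did not pass, with a rise of Cyp2b9 (5.65 ± 0.60). Across these 14, the median log2 change was 2.23 (camera adjusted p = 2.03e-10, adjusted p = 0.00758 with an estimated correlation), with 10 up and 0 down adjusted over the list alone. The male-biased genes moved as a group by a median log2 change of -2.93 (camera adjusted p = 2.96e-07, adjusted p = 0.407 with an estimated correlation), led by C6 (-2.93 ± 0.41), Gstp1 (-2.09 ± 0.32) and Cyp2d9 (-2.46 ± 0.40). Among the 15 measured, 0 rose, 12 fell and 3 did not pass, with 0 up and 13 down adjusted over the list alone.

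Amino acid stress genes rose on the MCD diet. Over the 18 measured integrated stress response genes the median log2 change was 1.81 (camera adjusted p = 1.07e-09, adjusted p = 0.0595 with an estimated correlation), with Asns (5.29 ± 0.41), Psat1 (5.91 ± 0.61) and Trib3 (4.20 ± 0.61). Singly, 12 rose, 0 fell and 6 did not pass, with 12 up and 0 down adjusted over the list alone. Fgf21, a stress-induced hepatokine, rose by 4.56 ± 0.90. Mat2a, the methionine adenosyltransferase form of growing liver, rose by 2.06 ± 0.29 (adjusted p = 1.15e-05), while Gnmt, which consumes S-adenosylmethionine, changed by -1.04 ± 0.25. Among 20 measured NRF2 target genes there were 6 rises, 2 falls and 12 not passing, led by Abcc4 (3.03 ± 0.40), Cbr3 (2.46 ± 0.43) and Srxn1 (2.09 ± 0.39). In median the 20 changed by 0.18 log2 (camera adjusted p = 0.0499, adjusted p = 0.493 with an estimated correlation), with 7 up and 3 down adjusted over the list alone. All 31 measured genes of amino acid catabolism and the urea cycle together had a median log2 change of -0.52 (camera adjusted p = 0.0175, adjusted p = 0.767 with an estimated correlation), led by Amdhd1 (-1.88 ± 0.28), Asl (-1.23 ± 0.26) and Hal (-1.40 ± 0.35). Of these 31, 1 rose, 10 fell and 20 did not pass, with 1 up and 10 down adjusted over the list alone. Scd1 (-2.43 ± 0.53) and Srebf1 (-1.69 ± 0.36) of lipogenesis fell, and the fatty acid transporter Cd36 rose by 2.21 ± 0.43. Of the 25 measured cholesterol synthesis genes, 3 rose, 1 fell and 21 did not pass, the fall being that of Tm7sf2 (-1.49 ± 0.40). Across these 25, the median log2 change was 0.57 (camera adjusted p = 0.0499, adjusted p = 0.767 with an estimated correlation), with 3 up and 1 down adjusted over the list alone.

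Proliferation, inflammation and matrix genes were also higher on the MCD diet. The cell cycle genes moved as a group by a median log2 change of 2.15 (camera adjusted p = 8.3e-12, adjusted p = 0.276 with an estimated correlation), led by Ccne1 (2.27 ± 0.36), Kif20a (3.06 ± 0.55) and Mcm2 (2.18 ± 0.40). Among the 30 measured, 22 rose, 0 fell and 8 did not pass, with 24 up and 1 down adjusted over the list alone. Ccnd1 rose by 3.18 ± 0.48 and Mki67 by 2.99 ± 0.63. Over the 16 measured p53 response genes the median log2 change was 0.65 (camera adjusted p = 0.0129, adjusted p = 0.365 with an estimated correlation), led by Tnfrsf10b (2.17 ± 0.46) and Trp53inp1 (1.55 ± 0.33). Singly, 4 rose, 0 fell and 12 did not pass, with 7 up and 0 down adjusted over the list alone. Among 17 measured recruited macrophage markers there were 11 rises, 1 fall and 5 not passing, led by Clec7a (3.94 ± 0.65), Trem2 (4.62 ± 0.82) and Itgax (2.90 ± 0.57). In median the 17 changed by 2.28 log2 (camera adjusted p = 2.31e-07, adjusted p = 0.411 with an estimated correlation), with 14 up and 1 down adjusted over the list alone. All 22 measured cytokine and chemokine genes together had a median log2 change of 1.27 (camera adjusted p = 6.6e-05, adjusted p = 0.493 with an estimated correlation), led by Ccl5 (1.76 ± 0.27) and Vcam1 (2.54 ± 0.55). Of these 22, 6 rose, 0 fell and 16 did not pass, with 7 up and 0 down adjusted over the list alone. Of the 27 measured matrix genes, 12 rose, 0 fell and 15 did not pass, led by Sparc (1.34 ± 0.22), Lum (1.64 ± 0.31) and Dcn (1.64 ± 0.32). Across these 27, the median log2 change was 1.15 (camera adjusted p = 9.21e-07, adjusted p = 0.411 with an estimated correlation), with 18 up and 1 down adjusted over the list alone. Timp1 rose by 3.60 ± 0.89. The stellate cell markers moved as a group by a median log2 change of 0.49 (camera adjusted p = 0.013, adjusted p = 0.407 with an estimated correlation), led by Pdgfra (1.90 ± 0.26) and Lrat (1.88 ± 0.33). Among the 14 measured, 5 rose, 0 fell and 9 did not pass, with 6 up and 0 down adjusted over the list alone. Well above background on only some arrays were Rd3 on 1 of the 4 MCD diet arrays, Serpina4-ps1 and Hnf4aos on 3 of the 4 MCD diet arrays, Cyp2a22 on 1 of the 4 standard diet arrays, Cyp2b9 on 2 of the 4 standard diet arrays and Sult1e1, Psat1, Pdgfra and Timp1 on 3 of the 4 standard diet arrays.

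In all, the MCD diet at baseline changed 5641 of 21691 genes, 2315 up and 3326 down, and 5068 from the arrays of its own slide alone. No overlap between the groups' arrays was found in 27.9% of all genes, against 2.86% by chance. Scaling to the array median gave 4416 up and 1224 down, as the median over all genes moved from -0.13 to 0.23, and quantile normalization gave 2810 up and 2509 down.

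**Figure D1:**
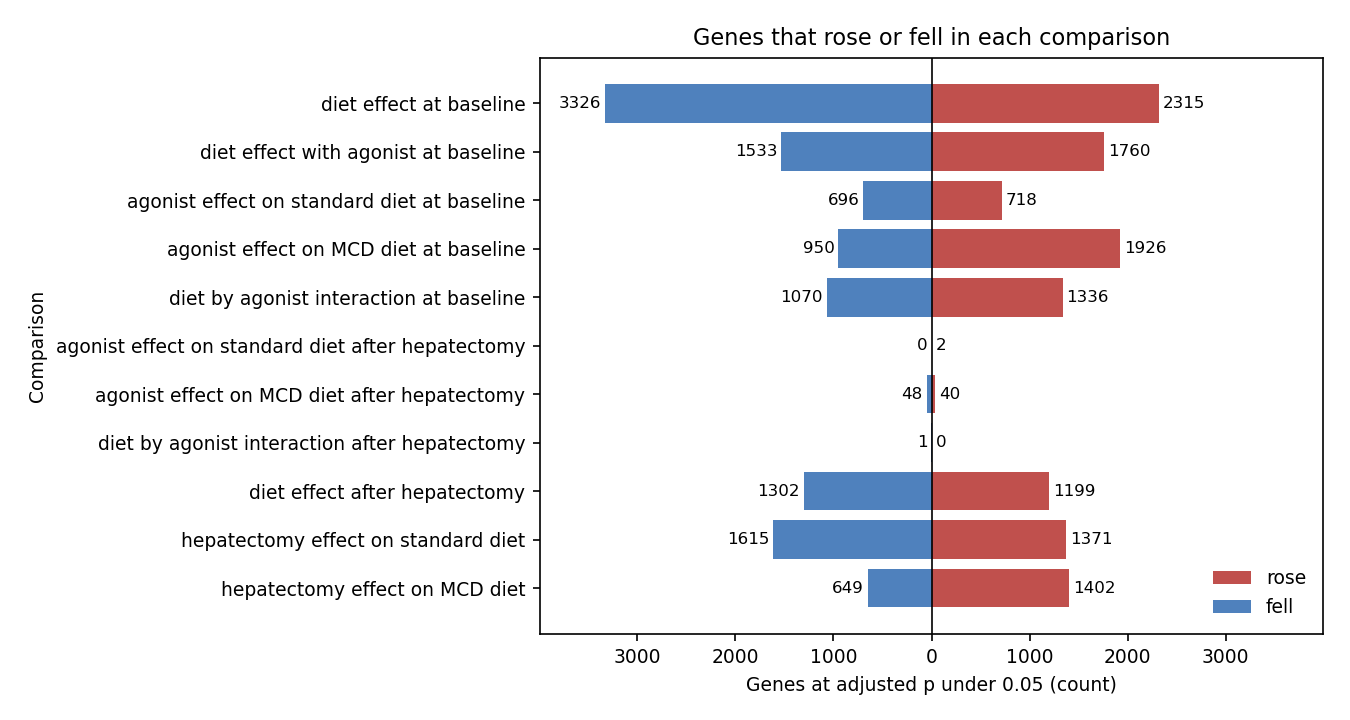
Genes that rose (right) and fell (left) at adjusted p under 0.05 in each of the 11 comparisons, as bars of gene counts on a linear axis from limma with n = 4 livers per group. The diet effect at baseline reaches 2315 up and 3326 down, while the agonist on standard diet after hepatectomy has 2 genes.

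Under the agonist, the MCD diet was again accompanied by female-pattern genes, and clock genes differed between the 2 groups. Cyp2b9 rose by 8.42 ± 0.60 (adjusted p = 1.13e-10; mm9 chromosome 7, 26983484 to 26983543) and Cyp2b10 by 7.06 ± 0.61 (adjusted p = 7.85e-09). The complement gene C6 changed by -4.30 ± 0.41 (adjusted p = 4.4e-08), the organic anion transporter Slco1a1 by -5.53 ± 1.47 and the desaturase Scd1 by -4.45 ± 0.57 (adjusted p = 7.54e-06). Other large rises were Sult1e1 (7.05 ± 1.43), Cyp2b13 (6.84 ± 0.30) and Cyp2a22 (at least 74.4-fold), and other large falls Serpina4-ps1 (-9.50 ± 2.01), Moxd1 (-6.04 ± 1.33), Elovl3 (-4.69 ± 1.34), Hspa1a (-4.63 ± 0.52) and Fos (at least 34.3-fold). Mat2a again rose, by 1.87 ± 0.29. Over the 14 measured female-biased genes the median log2 change was 3.56 (camera adjusted p = 1.35e-15, adjusted p = 0.000526 with an estimated correlation), with changes of Acot3 (5.61 ± 0.60) and Cyp3a44 (5.36 ± 0.64). Singly, 12 rose, 0 fell and 2 did not pass, with 12 up and 0 down adjusted over the list alone. Among 15 measured male-biased genes there were 0 rises, 9 falls and 6 not passing, with changes of Cyp4a12a (-4.01 ± 0.90) and Susd4 (-2.73 ± 0.62). In median the 15 changed by -2.73 log2 (camera adjusted p = 1.31e-08, adjusted p = 0.246 with an estimated correlation), with 0 up and 13 down adjusted over the list alone.

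Lipid storage and lipid synthesis genes moved apart in this contrast. All 20 measured lipogenic genes together had a median log2 change of -0.41 (camera adjusted p = 0.0217, adjusted p = 0.801 with an estimated correlation), with changes of Elovl6 (-2.36 ± 0.58), Acss2 (-1.88 ± 0.48) and Acacb (-1.88 ± 0.53). Of these 20, 0 rose, 5 fell and 15 did not pass, with 0 up and 6 down adjusted over the list alone. Of the 23 measured genes of lipid uptake and droplets, 6 rose, 0 fell and 17 did not pass, led by Vldlr (3.48 ± 0.46), Cidec (3.65 ± 0.64) and Cd36 (2.48 ± 0.43). Across these 23, the median log2 change was 0.30 (camera adjusted p = 0.0125, adjusted p = 0.246 with an estimated correlation), with 9 up and 0 down adjusted over the list alone. The ER chaperone genes moved as a group by a median log2 change of -0.78 (camera adjusted p = 1.12e-06, adjusted p = 0.246 with an estimated correlation), led by Sdf2l1 (-3.28 ± 0.42), Creld2 (-2.12 ± 0.38) and Pdia3 (-1.24 ± 0.24). Among the 18 measured, 0 rose, 7 fell and 11 did not pass, with 0 up and 8 down adjusted over the list alone. Over the 17 measured clock genes the median log2 change was 2.18 (camera adjusted p = 2.59e-06, adjusted p = 0.0982 with an estimated correlation), led by Ciart (at least 33-fold), Dbp (5.68 ± 0.83), Hlf (2.18 ± 0.25) and Nfil3 (-3.04 ± 0.47). Singly, 12 rose, 3 fell and 2 did not pass, with 12 up and 3 down adjusted over the list alone. Partly above background, on some arrays only, were Moxd1 and Hspa1a on 1 of the 4 MCD diet arrays, Serpina4-ps1 on 2 of the 4 MCD diet arrays, Cyp2b9, Cyp2b13 and Cyp3a44 on 1 of the 4 standard diet arrays and Sult1e1 and Vldlr on 3 of the 4 standard diet arrays. The diet contrast under agonist called 3293 genes, 1760 up and 1533 down, 1248 from its own slide alone and 1916 with normexp. In 14.2% of all genes the groups' arrays separated fully, against 2.86% by chance. Median scaling gave 1018 up and 1859 down, with the median over all genes at -0.13 instead of 0.03.

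Across genes, which are not independent replicates, the diet responses with and without agonist had r = 0.364 and rho = 0.253, and r = 0.206 without the filter on dim probes. Both contrasts called 1272 genes, 1090 of them in the same direction (590 up and 500 down, where independent lists would share 187.8 and 235.1). These 2 contrasts share no arrays, but both set row 2 of a slide against row 1, so a row effect may be shared.

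On standard diet at baseline, agonist-treated livers had more metallothionein and acute phase transcripts and a different clock state. Mt2 and Mt1, the metallothioneins, rose by 5.08 ± 0.82 (adjusted p = 0.000873; mm9 chromosome 8, 96697371 to 96697430) and 4.47 ± 0.71 (adjusted p = 0.000811), and Lcn2, an iron-binding acute phase protein, by 4.36 ± 0.99 (adjusted p = 0.0101). The clock repressor Nr1d1 changed by -3.69 ± 0.47 (adjusted p = 0.000136) and the coactivator Ppargc1b by -3.62 ± 0.54. Large changes were also seen for Prtn3 (4.18 ± 0.68), Scn3b (-3.12 ± 0.49), Hsd17b6 (-3.04 ± 0.55) and Gsta2 (-2.94 ± 0.57), and Mrgprg, Cbx8 and Rprd2 were at least 9.01-fold, at least 6.15-fold and at least 5.42-fold lower. For Pip5k1a (4.72 ± 1.01) only 2 of 3 probes and for Sybu (at least 4.93-fold higher) only 1 of 2 went this way. Among 22 measured acute phase genes there were 6 rises, 0 falls and 16 not passing, led by Apcs (2.50 ± 0.43), Steap4 (2.80 ± 0.55), Saa2 (3.88 ± 0.79) and Saa1 (3.71 ± 0.77). In median the 22 changed by 0.73 log2 (camera adjusted p = 1.56e-06, adjusted p = 0.285 with an estimated correlation), with 10 up and 0 down adjusted over the list alone. All 17 measured clock genes together had a median log2 change of -1.08 (camera adjusted p = 0.00055, adjusted p = 0.264 with an estimated correlation), besides Nr1d1 with Dbp (-3.95 ± 0.83), Hlf (-1.51 ± 0.25) and Arntl (2.40 ± 0.64). Of these 17, 1 rose, 6 fell and 10 did not pass, with 3 up and 8 down adjusted over the list alone.

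Drug-metabolism and fat-cell genes were lower and immune genes higher with the agonist on standard diet. Of the 25 measured xenobiotic P450 genes, 1 rose, 6 fell and 18 did not pass, led by Cyp2a4 (-1.84 ± 0.31), Cyp3a16 (-2.44 ± 0.45), Nr1i3 (-1.47 ± 0.30) and Cyp3a11 (-1.81 ± 0.40). Across these 25, the median log2 change was -0.63 (camera adjusted p = 0.000256, adjusted p = 0.264 with an estimated correlation), with 1 up and 7 down adjusted over the list alone. The adipocyte markers, of which Cidec, Fabp4 and Lipe also belong to the lipid droplet list, moved as a group by a median log2 change of -1.35 (camera adjusted p = 0.001, adjusted p = 0.0319 with an estimated correlation), led by Pparg (-0.84 ± 0.22). Among the 7 measured, 0 rose, 1 fell and 6 did not pass, with 0 up and 5 down adjusted over the list alone. Over the 30 measured genes of fatty acid oxidation the median log2 change was -0.34 (camera adjusted p = 0.00919, adjusted p = 0.625 with an estimated correlation), led by Acaa1b (-2.14 ± 0.44) and Acot1 (-2.64 ± 0.64). Singly, 1 rose, 2 fell and 27 did not pass, with 1 up and 3 down adjusted over the list alone. Srebf1 changed by -1.47 ± 0.36, and Igfbp1 and Socs2 rose by 1.58 ± 0.42 and 1.23 ± 0.32. Among 27 measured interferon response genes there were 7 rises, 0 falls and 20 not passing, led by Rtp4 (1.75 ± 0.35), Mx1 (2.27 ± 0.47) and Gbp3 (1.79 ± 0.48). In median the 27 changed by 0.87 log2 (camera adjusted p = 3.91e-09, adjusted p = 0.323 with an estimated correlation), with 12 up and 0 down adjusted over the list alone. All 13 measured Kupffer cell markers together had a median log2 change of 1.44 (camera adjusted p = 5.1e-07, adjusted p = 0.328 with an estimated correlation), led by Vsig4 (2.11 ± 0.45), Timd4 (1.75 ± 0.41) and Clec4f (1.49 ± 0.36). Of these 13, 6 rose, 0 fell and 7 did not pass, with 9 up and 0 down adjusted over the list alone. Above background on part of the arrays were Ppargc1b on 2 of the 4 agonist arrays, Mx1 on 1 of the 4 untreated arrays and Prtn3 on 2 of the 4 untreated arrays.

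The agonist on standard diet at baseline called 1414 genes, 718 up and 696 down, 267 from its own 2 groups alone and 812 without the filter on dim probes. It compares 2 slides, so slide and agonist cannot be told apart, and single arrays weighed on the count, which was 939 without standard diet replicate 1, 494 without agonist replicate 1 and 613 without agonist replicate 3. The arrays of the 2 groups did not overlap in 11.3% of all genes, where chance gives 2.86%. Median scaling gave 969 up and 297 down, the median over all genes moving from -0.01 to 0.17.

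On MCD diet at baseline the agonist was accompanied by lower proliferation, stress and macrophage genes. The mitotic genes Cdc20 and Prc1 changed by -3.71 ± 0.70 (adjusted p = 0.00175; mm9 chromosome 4, 118105534 to 118105593) and -3.50 ± 0.70 (adjusted p = 0.00257), and Aspm, Iqgap3 and Melk were at least 5.22-fold, at least 4.87-fold and at least 3.11-fold lower. Areg, which encodes the growth factor amphiregulin, was at least 5.41-fold lower (adjusted p = 0.000638), Tpx2 changed by -3.16 ± 0.80 and the P450 gene Cyp3a44 by -3.72 ± 0.64 (adjusted p = 0.00101). The chaperone gene Clgn rose by 2.83 ± 0.45 (adjusted p = 0.000703), the transcription factor gene Cux2 by 2.67 ± 0.82 and Vmn2r10 by 2.55 ± 0.51. Olfr48, Olfr136, Olfr259, Klk11 and Dnah3 were at least 4.54-fold, at least 2.29-fold, at least 2.92-fold, at least 1.83-fold and at least 1.68-fold higher. Of the 30 measured cell cycle genes, 0 rose, 14 fell and 16 did not pass, led by Cdk1 (at least 2.98-fold), Ccnb2 (-2.13 ± 0.41) and Kif20a (-2.44 ± 0.55). Across these 30, the median log2 change was -1.37 (camera adjusted p = 3.49e-12, adjusted p = 0.165 with an estimated correlation), with 0 up and 19 down adjusted over the list alone. The integrated stress response genes moved as a group by a median log2 change of -0.91 (camera adjusted p = 4.4e-06, adjusted p = 0.165 with an estimated correlation), led by Ddit3 (-2.05 ± 0.37), Nupr1 (-2.87 ± 0.61), Gdf15 (-2.39 ± 0.55) and Atf3 (-3.15 ± 0.79). Among the 18 measured, 0 rose, 5 fell and 13 did not pass, with 0 up and 6 down adjusted over the list alone. Mki67 changed by -2.29 ± 0.63 and Scd1 by -1.76 ± 0.53.

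Over the 24 measured growth factor and regeneration genes the median log2 change was -0.58 (camera adjusted p = 0.00074, adjusted p = 0.019 with an estimated correlation), with Areg and Hgf (-1.84 ± 0.37), Fos (at least 5.5-fold) and Il6st (-0.97 ± 0.24). Singly, 1 rose, 6 fell and 17 did not pass, with 2 up and 7 down adjusted over the list alone. Among 13 measured Kupffer cell markers there were 0 rises, 6 falls and 7 not passing, led by Folr2 (-2.19 ± 0.42), Vsig4 (-1.93 ± 0.45) and Cd5l (-1.46 ± 0.40). In median the 13 changed by -1.25 log2 (camera adjusted p = 8.29e-08, adjusted p = 0.263 with an estimated correlation), with 0 up and 11 down adjusted over the list alone. All 15 measured endothelial markers together had a median log2 change of -0.39 (camera adjusted p = 0.012, adjusted p = 0.459 with an estimated correlation), led by Oit3 (-1.57 ± 0.34) and Bmp2 (-0.83 ± 0.28). Of these 15, 0 rose, 2 fell and 13 did not pass, with 0 up and 2 down adjusted over the list alone. Well above background on only some arrays were Tpx2 and Dnah3 on 1 of the 4 agonist arrays, Olfr136, Olfr259 and Klk11 on 2 of the 4 agonist arrays, Kif20a and Hgf on 3 of the 4 agonist arrays, Clgn on 1 of the 4 untreated arrays, Vmn2r10 on 2 of the 4 untreated arrays and Fos on 3 of the 4 untreated arrays. The agonist on MCD diet called 2876 genes, 1926 up and 950 down, and 1938 from its own groups alone, 6846 with normexp and 5404 without the filter on dim probes. This contrast too runs across slides, it shares the MCD diet arrays with the diet effect with opposite sign, and it called 1816 without MCD diet replicate 4 and 1470 without agonist replicate 3. No overlap between the groups' arrays was found in 18.4% of all genes, against 2.86% by chance. The split turned to 444 up and 2179 down under median scaling and to 1212 and 1219 under quantile normalization, with medians over all genes of 0.14 before and -0.20 with median scaling.

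Whether the agonist acted differently on the 2 diets at baseline was tested as an interaction, the agonist effect on MCD diet minus that on standard diet. Chemokine and macrophage genes had the more negative agonist effect on MCD diet, with Ccl2 (-5.37 ± 1.37, adjusted p = 0.0121) and Ms4a6d (-5.33 ± 1.08, adjusted p = 0.00279) among the largest differences. The neurotrophic factor gene Artn (-5.38 ± 0.98), the lipocalin Lcn2 (-5.18 ± 1.40) and Egr2 (-5.20 ± 1.43) went the same way. In the other direction lay the coactivator gene Ppargc1b (4.87 ± 0.77, adjusted p = 0.000423), the clock genes Nr1d1 (4.18 ± 0.66) and Dbp (4.45 ± 1.18), and Adam11 (3.97 ± 0.80) and Cyp2b10 (3.59 ± 0.87). Srebf1 differed by 2.35 ± 0.51, Igfbp1 by -2.52 ± 0.60, Mki67 by -3.30 ± 0.90 and Adgre1 by -3.44 ± 0.81, and Cdkn1a by -3.21 ± 1.03 on 1 of its 2 probes. For interactions, a rise or fall of a listed gene means a difference above or below 0. Of 18 lists called here, the growth factor list alone held with an estimated correlation. Of the 24 measured growth factor and regeneration genes, 2 rose, 5 fell and 17 did not pass. Across these 24, the median log2 change was -0.83 (camera adjusted p = 0.00192, adjusted p = 0.0397 with an estimated correlation), with 2 up and 5 down adjusted over the list alone. The Kupffer cell markers moved as a group by a median log2 change of -2.73 (camera adjusted p = 1.2e-12, adjusted p = 0.154 with an estimated correlation), led by Vsig4 (-4.04 ± 0.63), Clec4f (-2.73 ± 0.51) and Timd4 (-3.06 ± 0.57). Among the 13 measured, 0 rose, 10 fell and 3 did not pass, with 0 up and 10 down adjusted over the list alone. Over the 22 measured cytokine and chemokine genes the median log2 change was -2.47 (camera adjusted p = 6.7e-11, adjusted p = 0.154 with an estimated correlation), led by Tlr4 (-2.73 ± 0.54), Ccl5 (-1.88 ± 0.39) and Tnfaip3 (-4.07 ± 1.02). Singly, 0 rose, 13 fell and 9 did not pass, with 0 up and 15 down adjusted over the list alone. Among 17 measured T, NK and B cell markers there were 1 rise, 4 falls and 12 not passing, led by Cd3d (-1.82 ± 0.37), Lck (-1.34 ± 0.30) and Cd4 (2.15 ± 0.51). In median the 17 changed by -0.52 log2 (camera adjusted p = 0.048, adjusted p = 0.471 with an estimated correlation), with 2 up and 6 down adjusted over the list alone. Partly above background were Ppargc1b on 2 of the 4 standard diet with agonist arrays; Artn, Ms4a6d and Egr2 on 1 of the 4 standard diet arrays and 1 of the 4 MCD diet with agonist arrays; Tlr4 on 3 of the 4 standard diet arrays and 1 of the 4 MCD diet with agonist arrays; Timd4 on 3 of the 4 MCD diet with agonist arrays.

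The baseline interaction called 2406 genes, 1336 above and 1070 below 0, and 1619 from the 4 groups alone. Median scaling gave 262 above and 2460 below 0, with the median over all genes moving from 0.18 to -0.35, and quantile normalization gave 1007 and 1273.

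**Figure D2:**
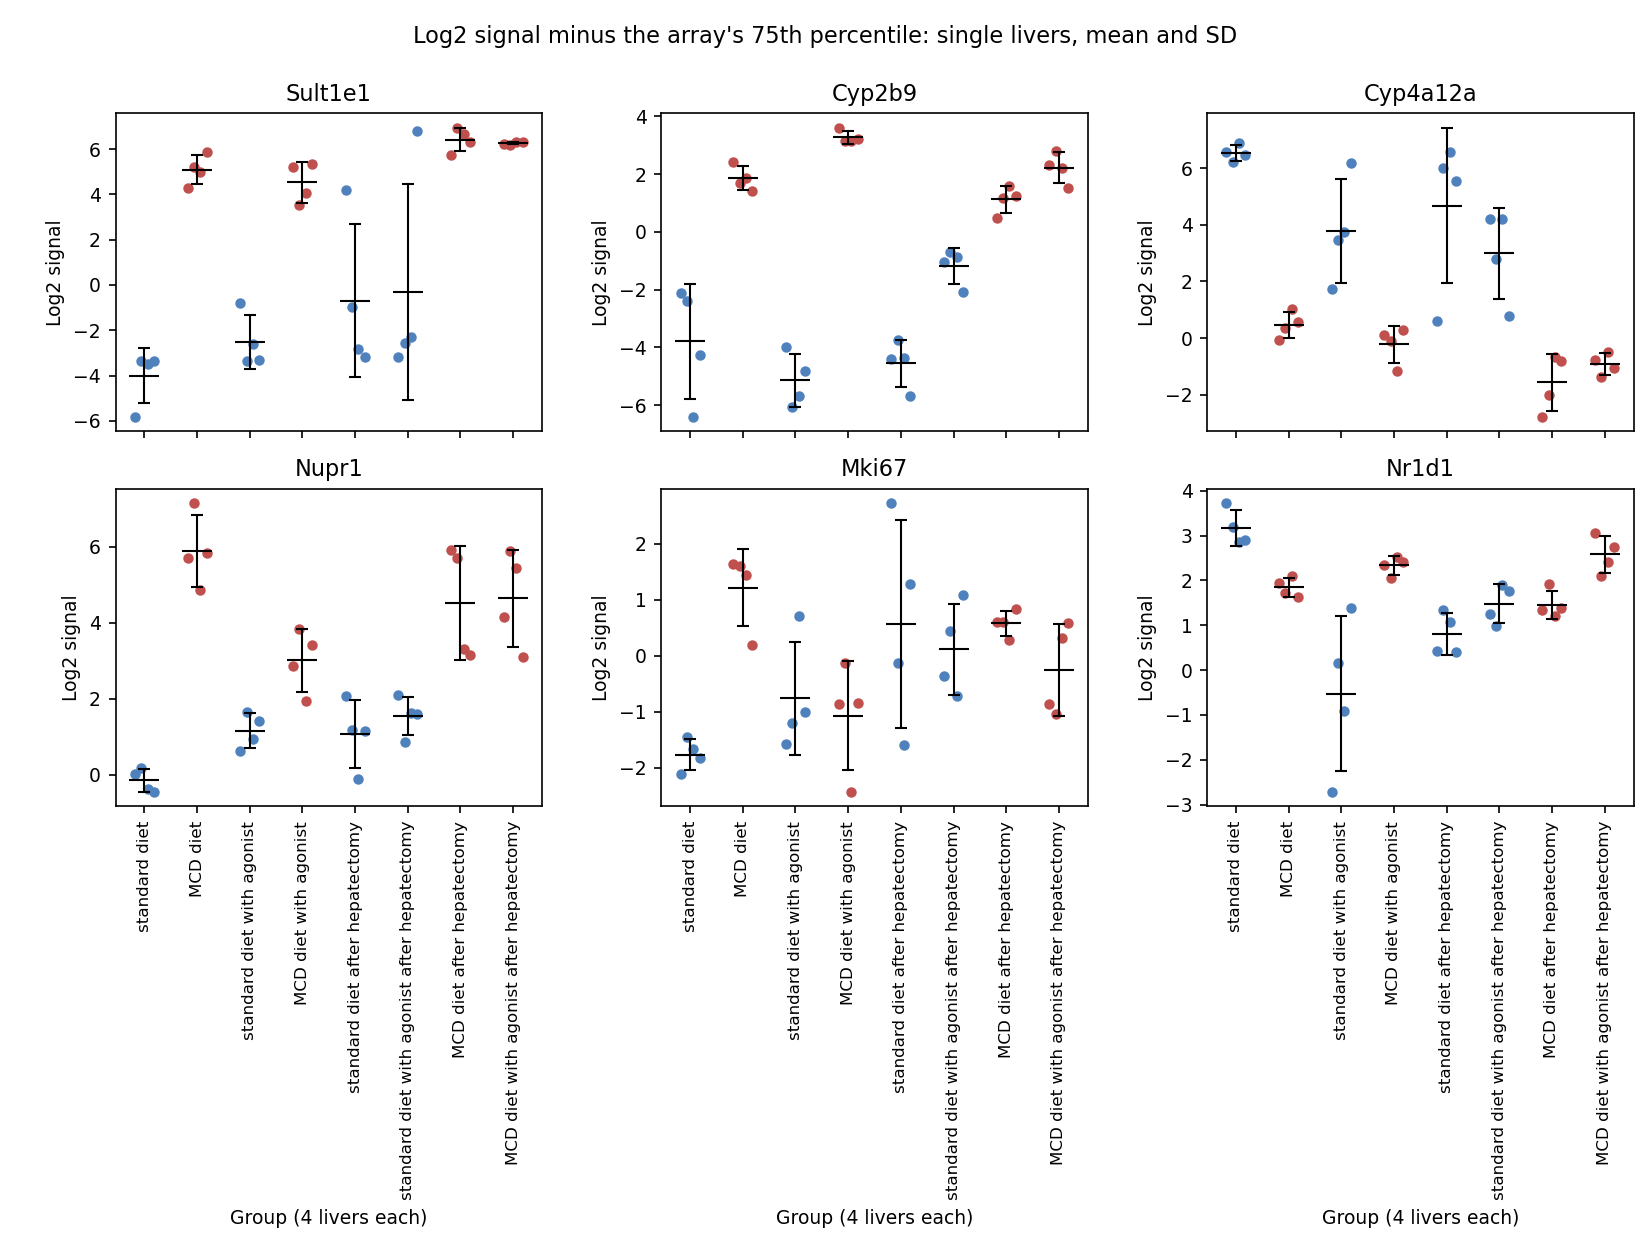
Log2 signal relative to each array's 75th percentile for 6 named genes in the 8 groups, as points for single livers and bars for the mean ± SD (n = 4). The group means of Sult1e1 and Cyp2b9 lie higher and those of Cyp4a12a lower on MCD diet, and standard diet after hepatectomy replicate 1 (Sult1e1 and Cyp4a12a) and, for Sult1e1, standard diet with agonist after hepatectomy replicate 4 lie apart from their groups.

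After hepatectomy on standard diet, the agonist was accompanied by higher expression of 2 female-predominant P450 genes. Cyp2b13 (mm9 chromosome 7, 26880905 to 26880964) was at least 2.38-fold higher (adjusted p = 3.08e-05) and Cyp2b9 rose by 3.37 ± 0.60 (adjusted p = 0.0495), being well above background on 2 of the 4 untreated arrays. All 14 measured female-biased genes together had a median log2 change of 0.81 (camera adjusted p = 2.09e-14, adjusted p = 0.000895 with an estimated correlation). Of these 14, 2 rose, 0 fell and 12 did not pass, with 4 up and 0 down adjusted over the list alone. Of the 7 measured adipocyte markers, 0 rose, 0 fell and 7 did not pass. Across these 7, the median log2 change was -0.19 (camera adjusted p = 0.000251, adjusted p = 0.00556 with an estimated correlation), with 0 up and 2 down adjusted over the list alone. The cell cycle genes moved as a group by a median log2 change of -0.64 (camera adjusted p = 1.09e-08, adjusted p = 0.359 with an estimated correlation). Among the 30 measured, 0 rose, 0 fell and 30 did not pass, with 0 up and 0 down adjusted over the list alone. Standard diet replicate 1 scored 1.85 on this list (others -0.53 to 0.76), and without it and agonist replicate 4 the adjusted p was 0.0237. Of 13 lists called, 2 held with an estimated correlation. Besides the cell cycle, the interferon (8.5e-06), ER chaperone (9.4e-05), recruited macrophage (0.0103), matrix (0.025), male-biased (0.0262) and T, NK and B cell (0.042) lists were lower by camera adjusted p, and the P450 (2.02e-05), stress response (0.000405), cholesterol (0.00466) and clock (0.0497) lists higher (adjusted p = 0.166 to 0.689 with an estimated correlation). The interferon, matrix, T, NK and B cell, P450 and clock lists were not called without the 2 arrays. The 2 genes were the only calls among 21691, 3 were called from the arrays of the slide alone, and 557 had an unadjusted p under 0.05. In 2.81% of all genes the groups' arrays separated fully, against 2.86% by chance. On this slide standard diet replicate 1 and agonist replicate 4 carried high recruited macrophage scores (2.94 and 2.23), and the count was 7 without standard diet replicate 1, and 1 without standard diet replicate 2 or 4 or agonist replicate 2 or 3. Without both high arrays Cyp2b9 (3.72 ± 0.69, adjusted p = 0.0813) missed the threshold on fewer arrays, with a change no smaller than before. With normexp the count was 0, and it was 1 with quantile normalization, no filter, the mean over probes or outlier spots kept. The Cyp2b9 call was lost in 13 of 17 alternatives, single arrays left out included.

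After hepatectomy on MCD diet, immune and acute phase lists were lower with the agonist, though none of the 10 lists called held with an estimated correlation. Prtn3, a neutrophil protease, changed by -2.94 ± 0.68 (adjusted p = 0.0468; mm9 chromosome 10, 79343869 to 79344685), the antibody-joining gene Jchain by -2.55 ± 0.55 (adjusted p = 0.0311), Ighv1-77 by -2.67 ± 0.59 and Isyna1, which makes inositol phosphate, by -2.12 ± 0.41 (adjusted p = 0.0186). Further falls were Crybb3 (-2.57 ± 0.44), Ly6a2 (-2.82 ± 0.60), Hsd3b4 (-2.33 ± 0.55) and Tnfrsf17 (at least 1.16-fold). The transcription factor genes Foxo3 and Smad9 rose by 2.25 ± 0.32 (adjusted p = 0.00283) and 1.79 ± 0.33, Reg2 and Etd were at least 4.24-fold and at least 1.92-fold higher, and Armcx5 (1.77 ± 0.36), Taf1b (1.72 ± 0.36), Cyp3a25 (1.44 ± 0.34) and Tlk2 (1.40 ± 0.27) rose as well. Over the 12 measured neutrophil markers the median log2 change was -2.22 (camera adjusted p = 4.1e-08, adjusted p = 0.16 with an estimated correlation). Singly, 0 rose, 0 fell and 12 did not pass, with 0 up and 8 down adjusted over the list alone. Ltf (-3.93 ± 1.05) and Camp (-3.76 ± 1.02) had the smallest adjusted p of these markers and did not pass (adjusted p = 0.0842 and adjusted p = 0.0908). Acute phase (8.53e-07), recruited macrophage (5.45e-05), cytokine (8.82e-05), Kupffer cell (0.000594) and T, NK and B cell (0.000594) lists were lower by camera adjusted p, and the bile acid list (0.045) higher, with 0 members passing (adjusted p = 0.326 to 0.645 with an estimated correlation). Among 6 measured erythroid markers there were 0 rises, 0 falls and 6 not passing. In median the 6 changed by -0.90 log2 (camera adjusted p = 0.000594, adjusted p = 0.377 with an estimated correlation), with 0 up and 5 down adjusted over the list alone. All 35 measured nuclear genes of the respiratory chain together had a median log2 change of 0.36 (camera adjusted p = 0.0012, adjusted p = 0.645 with an estimated correlation). Of these 35, 0 rose, 0 fell and 35 did not pass, with 1 up and 0 down adjusted over the list alone. Of the 9 measured pancreatic acinar markers, 1 rose, 0 fell and 8 did not pass, led by Try4 (3.60 ± 0.83). Across these 9, the median log2 change was 1.64 (camera adjusted p = 8.53e-07, adjusted p = 0.16 with an estimated correlation), with 6 up and 0 down adjusted over the list alone.

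Acinar scores were highest in agonist replicates 1 and 4 (3.73 and 2.74), and without these arrays the acinar list had an adjusted p of 0.311, the respiratory chain list 0.172, the bile acid list 0.431 and the neutrophil list 1.56e-09, and the other 6 were still called. Without them Reg2 (adjusted p = 0.117) and Try4 (1.59 ± 0.79, adjusted p = 0.495) no longer passed, Try4 keeping 44.2% of its change. On the fewer arrays Cyp3a25 (1.23 ± 0.42, adjusted p = 0.257), Hsd3b4 (-2.78 ± 0.68, adjusted p = 0.067), Taf1b (1.95 ± 0.45, adjusted p = 0.0513) and Tlk2 (1.45 ± 0.34, adjusted p = 0.0545) missed the threshold too, but at 85.7% to 119% of their change. Partly above background, on some arrays only, were Ighv1-77 and Ly6a2 on 1 of the 4 agonist arrays, Hsd3b4, Etd and Ltf on 3 of the 4 agonist arrays, Tnfrsf17 on 1 of the 4 untreated arrays and Taf1b and Try4 on 2 of the 4 untreated arrays. The agonist on MCD diet after hepatectomy called 88 genes, 40 up and 48 down, 66 from its own slide alone, 165 with normexp and 22 without the filter, with 2986 at an unadjusted p under 0.05. The arrays of the 2 groups did not overlap in 10.2% of all genes, where chance gives 2.86%. The count was 19, 17 and 290 without MCD diet replicates 1, 2 and 4, and 32, 26 and 18 without agonist replicates 1, 2 and 3. Median scaling gave 25 up and 53 down.

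The interaction of diet and agonist after hepatectomy called 1 gene, Cyp2b13, whose agonist effect was lower on MCD diet (adjusted p = 0.0295). It was not well above background on any untreated standard diet array, so no size is given. The count was 0 with normexp, median scaling, quantile normalization, no filter on dim probes or the replicate block. The female-biased genes moved as a group by a median log2 change of -0.75 (camera adjusted p = 2.32e-06, adjusted p = 0.0491 with an estimated correlation). Among the 14 measured, 0 rose, 1 fell and 13 did not pass, with 0 up and 5 down adjusted over the list alone. Over the 7 measured adipocyte markers the median log2 change was 0.79 (camera adjusted p = 0.000785, adjusted p = 0.0249 with an estimated correlation). Singly, 0 rose, 0 fell and 7 did not pass, with 1 up and 0 down adjusted over the list alone. Among 12 measured neutrophil markers there were 0 rises, 0 falls and 12 not passing. In median the 12 changed by -2.75 log2 (camera adjusted p = 3.32e-08, adjusted p = 0.103 with an estimated correlation), with 0 up and 6 down adjusted over the list alone. The 4 groups alone gave 1 gene and 1032 genes had an unadjusted p under 0.05. Without the 2 arrays with high acinar scores, on fewer arrays, Cyp2b13 had an adjusted p of 0.0772. Without standard diet replicate 1 the count was 4 and without MCD diet with agonist replicate 1 it was 3. It was 0 without any one of 11 other arrays, namely standard diet 2 and 3, standard diet with agonist 1, 2 and 3, MCD diet 1, 3 and 4, and MCD diet with agonist 2, 3 and 4.

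Across genes the agonist responses of the 2 diets after hepatectomy had r = 0.246 and rho = 0.247, but r = 0.0724 without standard diet replicate 1 and 0.108 without both arrays of high macrophage score. Before and after hepatectomy, the agonist responses had r = -0.00285 and rho = 0.011 on standard diet, and r = 0.298 and rho = 0.229 on MCD diet. The latter r turned to -0.0238 with normexp and -0.00129 without the filter on dim probes, and was 0.185 without the acinar arrays. On MCD diet 32 genes were called both before and after, 31 in the same direction (10 up and 21 down, where independent lists would share 3.55 and 2.10). No arrays are shared between the contrasts of any of these pairs.

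After hepatectomy the MCD diet was again accompanied by a female pattern and by stress genes. Sult1e1 rose by 7.11 ± 1.43 (adjusted p = 0.00148) and Cyp3a44 by 9.03 ± 0.64 (adjusted p = 2.37e-10; mm9 chromosome 5, 146585717 to 146585776). Fgf21 rose by 7.06 ± 0.90 (adjusted p = 6.01e-06), Mfsd2a, a lysophospholipid transporter gene, by 5.91 ± 0.64 and the droplet gene Cidec by 5.53 ± 0.64. Cyp4a12a changed by -6.23 ± 0.90 (adjusted p = 3.51e-05) and Cyp4a12b by -5.74 ± 0.86. Other large changes were Radx (6.16 ± 0.64), Cyp2b9 (5.68 ± 0.60), Hnf4aos (-5.64 ± 0.73), Susd4 (-4.61 ± 0.62), Lrit1 (-4.54 ± 0.58), Dct (-4.46 ± 0.66) and Sntg2 (-4.39 ± 0.64), and Lrit2 was at least 5.24-fold lower. All 14 measured female-biased genes together had a median log2 change of 2.14 (camera adjusted p = 3.08e-13, adjusted p = 0.00155 with an estimated correlation), with Cyp2b13 (at least 16.9-fold) and Cyp2a4 (1.88 ± 0.29). Of these 14, 8 rose, 0 fell and 6 did not pass, with 9 up and 0 down adjusted over the list alone. Of the 18 measured integrated stress response genes, 11 rose, 0 fell and 7 did not pass, with Asns (3.38 ± 0.41), Psat1 (4.47 ± 0.61) and Aldh1l2 (3.38 ± 0.51). Across these 18, the median log2 change was 1.21 (camera adjusted p = 1.79e-12, adjusted p = 0.018 with an estimated correlation), with 12 up and 0 down adjusted over the list alone. The methionine and choline genes moved as a group by a median log2 change of -0.42 (camera adjusted p = 0.00803, adjusted p = 0.389 with an estimated correlation), with Mat2a (1.52 ± 0.29), Sardh (-1.28 ± 0.25), Chka (-1.22 ± 0.25) and Cth (-1.53 ± 0.36). Among the 23 measured, 1 rose, 6 fell and 16 did not pass, with 1 up and 8 down adjusted over the list alone.

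Over the 12 measured neutrophil markers the median log2 change was 2.44 (camera adjusted p = 3.25e-05, adjusted p = 0.267 with an estimated correlation), led by S100a8 (3.00 ± 0.65), S100a9 (2.48 ± 0.63) and Camp (3.51 ± 1.02). Singly, 6 rose, 0 fell and 6 did not pass, with 8 up and 0 down adjusted over the list alone. Among 6 measured muscle markers there were 0 rises, 0 falls and 6 not passing. In median the 6 changed by -1.10 log2 (camera adjusted p = 0.0259, adjusted p = 0.328 with an estimated correlation), with 0 up and 4 down adjusted over the list alone. Scd1 (-2.79 ± 0.53), Srebf1 (-1.59 ± 0.36), Gnmt (-1.06 ± 0.25), Bhmt (-1.09 ± 0.34) and Acta2 (-2.18 ± 0.58) fell, while Cpt1a (0.88 ± 0.22), Ccnd1 (1.56 ± 0.48), Igfbp1 (1.36 ± 0.42) and Pck1 (1.09 ± 0.34) rose. Igf1 (-0.99 ± 0.28) fell on 4 of its 5 probes. Above background on part of the arrays were Hnf4aos, Lrit1 and Sntg2 on 2 of the 4 MCD diet arrays, Radx on 1 of the 4 standard diet arrays and Cyp3a44, Cyp2b9 and Aldh1l2 on 2 of the 4 standard diet arrays.

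The diet effect after hepatectomy called 2501 genes, 1199 up and 1302 down, and 1557 from its own 2 groups, which lie on different slides. No overlap between the groups' arrays was found in 16.9% of all genes, against 2.86% by chance. The count was 1552, 1533 and 1488 without standard diet replicate 2, standard diet replicate 3 and MCD diet replicate 2. Standard diet replicate 1 resembled the MCD arrays, with a position of 0.824 on an axis from standard (0) to MCD diet (1), and without it and agonist replicate 4 the count was 3092 and the muscle list had an adjusted p of 0.173, while Acta2 (-1.64 ± 0.57, adjusted p = 0.0549), Camp (2.85 ± 1.02, adjusted p = 0.0601), Igfbp1 (1.29 ± 0.45, adjusted p = 0.0554) and Pck1 (1.00 ± 0.37, adjusted p = 0.0721) no longer passed on the fewer arrays, at 75.2% to 95.2% of their change. Median scaling gave 1363 up and 835 down.

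Regenerated livers on standard diet had more macrophage, matrix and proliferation transcripts than livers at baseline. Chil3, a chitinase-like macrophage gene, rose by 4.88 ± 1.13 (adjusted p = 0.00516), S100a8 by 3.79 ± 0.65 (adjusted p = 0.000552; mm9 chromosome 3, 90473778 to 90473837), Lcn2 by 4.36 ± 0.99 and Timp1 by 3.78 ± 0.89. The topoisomerase gene Top2a was at least 6.71-fold higher (adjusted p = 0.00136), and Orm3 (3.90 ± 0.97), F13a1 (3.88 ± 0.84) and Prtn3 (3.73 ± 0.68) rose. Rgs16, a regulator of G-protein signalling, changed by -5.30 ± 0.98 (adjusted p = 0.00101), the mRNA-decay factor Zfp36 by -3.25 ± 0.44 (adjusted p = 4.85e-05) and Fgf21 by -3.26 ± 0.90. Further falls were Ppp1r3g (-4.11 ± 0.81), Tbx22 (-3.99 ± 0.99), Pax2 (-3.33 ± 1.08), Olfr433 (at least 6.5-fold) and Hdgfl1 (at least 5.47-fold). All 27 measured matrix genes together had a median log2 change of 1.00 (camera adjusted p = 1.55e-09, adjusted p = 0.412 with an estimated correlation), led by Sparc (2.10 ± 0.22), Col3a1 (2.34 ± 0.38) and Col1a2 (2.25 ± 0.41). Of these 27, 14 rose, 0 fell and 13 did not pass, with 17 up and 0 down adjusted over the list alone. Of the 30 measured cell cycle genes, 17 rose, 0 fell and 13 did not pass, with Top2a, Cenpe (3.17 ± 0.65), Ccnb2 (1.86 ± 0.41) and Cdc20 (2.87 ± 0.70). Across these 30, the median log2 change was 1.61 (camera adjusted p = 2.95e-10, adjusted p = 0.402 with an estimated correlation), with 22 up and 0 down adjusted over the list alone. The Kupffer cell markers moved as a group by a median log2 change of 1.80 (camera adjusted p = 1.55e-09, adjusted p = 0.402 with an estimated correlation), led by Vsig4 (2.03 ± 0.45) and Timd4 (1.79 ± 0.41). Among the 13 measured, 11 rose, 0 fell and 2 did not pass, with 12 up and 0 down adjusted over the list alone. Over the 17 measured recruited macrophage markers the median log2 change was 2.08 (camera adjusted p = 1.37e-08, adjusted p = 0.43 with an estimated correlation), led by Clec7a (3.25 ± 0.65) and Cx3cr1 (3.14 ± 0.73). Singly, 11 rose, 0 fell and 6 did not pass, with 13 up and 0 down adjusted over the list alone. Among 22 measured bile acid genes there were 0 rises, 1 fall and 21 not passing, led by Abcg5 (-1.14 ± 0.30). In median the 22 changed by -0.49 log2 (camera adjusted p = 0.0435, adjusted p = 0.511 with an estimated correlation), with 0 up and 1 down adjusted over the list alone.

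Cd36 rose by 1.49 ± 0.43, Col1a1 by 2.77 ± 0.64, Cd68 by 2.08 ± 0.52 and Mki67 by 2.34 ± 0.63, while Cpt1a (-0.65 ± 0.22) and Gnmt (-0.82 ± 0.25) fell. Well above background on only some arrays were Tbx22 on 2 of the 4 regenerated arrays, Top2a and Ppp1r3g on 3 of the 4 regenerated arrays, F13a1 on 1 of the 4 baseline arrays, Chil3 and Prtn3 on 2 of the 4 baseline arrays and Timp1 and Cenpe on 3 of the 4 baseline arrays. Hepatectomy on standard diet called 2986 genes, 1371 up and 1615 down, 1061 from its own 2 groups and 4627 with normexp, across 2 slides and 2 scan sessions that cannot be told apart from it. In 17.5% of all genes the groups' arrays separated fully, against 2.86% by chance. Without regenerated replicate 1 the count was 1562, and without it and agonist replicate 4 Mki67 (1.62 ± 0.58, adjusted p = 0.0821), Cpt1a (-0.46 ± 0.22, adjusted p = 0.205), Gnmt (-0.52 ± 0.24, adjusted p = 0.172) and Tbx22 (-3.24 ± 1.03, adjusted p = 0.0501) no longer passed, at 64.1% to 81.4% of their change, nor did the bile acid list (0.214). That array had the highest matrix score (1.67, others -0.39 to 0.44) and cell cycle score (1.85, others -0.53 to 0.76) of its group. Without both arrays the adjusted p was 2e-06 for the matrix, 1.83e-06 for the cell cycle, 2.69e-07 for the Kupffer cell and 8.5e-07 for the recruited macrophage list. Median scaling gave 1722 up and 822 down, and quantile normalization 1787 and 1234.

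Regenerated livers on MCD diet had higher neutrophil and acute phase lists and lower cell cycle and respiratory chain lists than MCD livers at baseline. Prtn3 rose by 4.84 ± 0.68 (adjusted p = 8.3e-05), the B cell chemokine gene Cxcl13 by 4.58 ± 0.79 (adjusted p = 0.00056; mm9 chromosome 5, 96389861 to 96389920), S100a8 by 3.74 ± 0.65 (adjusted p = 0.000639) and Igdcc4 by 5.76 ± 0.97. The keratin gene Krt23 changed by -3.86 ± 0.66 (adjusted p = 0.000555), the growth-arrest gene Gadd45a by -2.90 ± 0.63 and the hepcidin paralog Hamp2 by -2.79 ± 0.58. Other large rises were Rnf138rt1 (4.41 ± 0.93), Tmc5 (4.35 ± 0.88), Chil3 (3.73 ± 1.13) and Dmkn (at least 5.74-fold), and other large falls Slc26a4 (-3.80 ± 0.71), Clec2h (-3.61 ± 0.98), Kifc1 (at least 3.21-fold) and Scube3 (at least 2.21-fold). N6amt1 (-3.51 ± 0.35) fell on 1 of 2 probes only. None of the 16 lists called in this comparison held with an estimated correlation. All 12 measured neutrophil markers together had a median log2 change of 2.98 (camera adjusted p = 4.16e-06, adjusted p = 0.479 with an estimated correlation). Of these 12, 6 rose, 0 fell and 6 did not pass, with 9 up and 0 down adjusted over the list alone. Of the 22 measured acute phase genes, 8 rose, 0 fell and 14 did not pass, led by Cp (1.13 ± 0.22), Fga (1.46 ± 0.34), Orm1 (1.33 ± 0.35) and Orm3 (3.54 ± 0.97). Across these 22, the median log2 change was 0.96 (camera adjusted p = 0.000222, adjusted p = 0.479 with an estimated correlation), with 11 up and 1 down adjusted over the list alone. The nuclear genes of the respiratory chain moved as a group by a median log2 change of -0.45 (camera adjusted p = 2.42e-05, adjusted p = 0.479 with an estimated correlation), led by Ndufb9 (-0.87 ± 0.27), Ndufs1 (-0.68 ± 0.21) and Uqcrb (-0.72 ± 0.23). Among the 35 measured, 0 rose, 4 fell and 31 did not pass, with 0 up and 6 down adjusted over the list alone. Over the 14 measured pericentral hepatocyte markers the median log2 change was -0.64 (camera adjusted p = 0.0172, adjusted p = 0.661 with an estimated correlation). Singly, 0 rose, 0 fell and 14 did not pass, with 0 up and 4 down adjusted over the list alone. Glul (-1.40 ± 0.48, adjusted p = 0.0592) did not pass. Among 30 measured cell cycle genes there were 0 rises, 2 falls and 28 not passing, led by Kif20a (-2.06 ± 0.55) and Cdc20 (-2.18 ± 0.70). In median the 30 changed by -0.56 log2 (camera adjusted p = 0.00499, adjusted p = 0.661 with an estimated correlation), with 0 up and 1 down adjusted over the list alone.

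Cd36 rose by 1.49 ± 0.43, and Bhmt (-1.13 ± 0.34) and Gnmt (-0.83 ± 0.25) fell. Partly above background, on some arrays only, were Slc26a4 on 1 of the 4 regenerated arrays, Clec2h on 2 of the 4 regenerated arrays, Tmc5 on 1 of the 4 baseline arrays, Prtn3 and Igdcc4 on 2 of the 4 baseline arrays and Rnf138rt1 on 3 of the 4 baseline arrays. Hepatectomy on MCD diet called 2051 genes, 1402 up and 649 down, 2439 from its own 2 groups and 1286 with normexp, again across slides and scan sessions. The arrays of the 2 groups did not overlap in 19% of all genes, where chance gives 2.86%. Median scaling gave 890 up and 808 down, with the median over all genes at -0.11 instead of -0.02. Whether hepatectomy acted differently on the 2 diets was not tested.

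**Figure D3:**
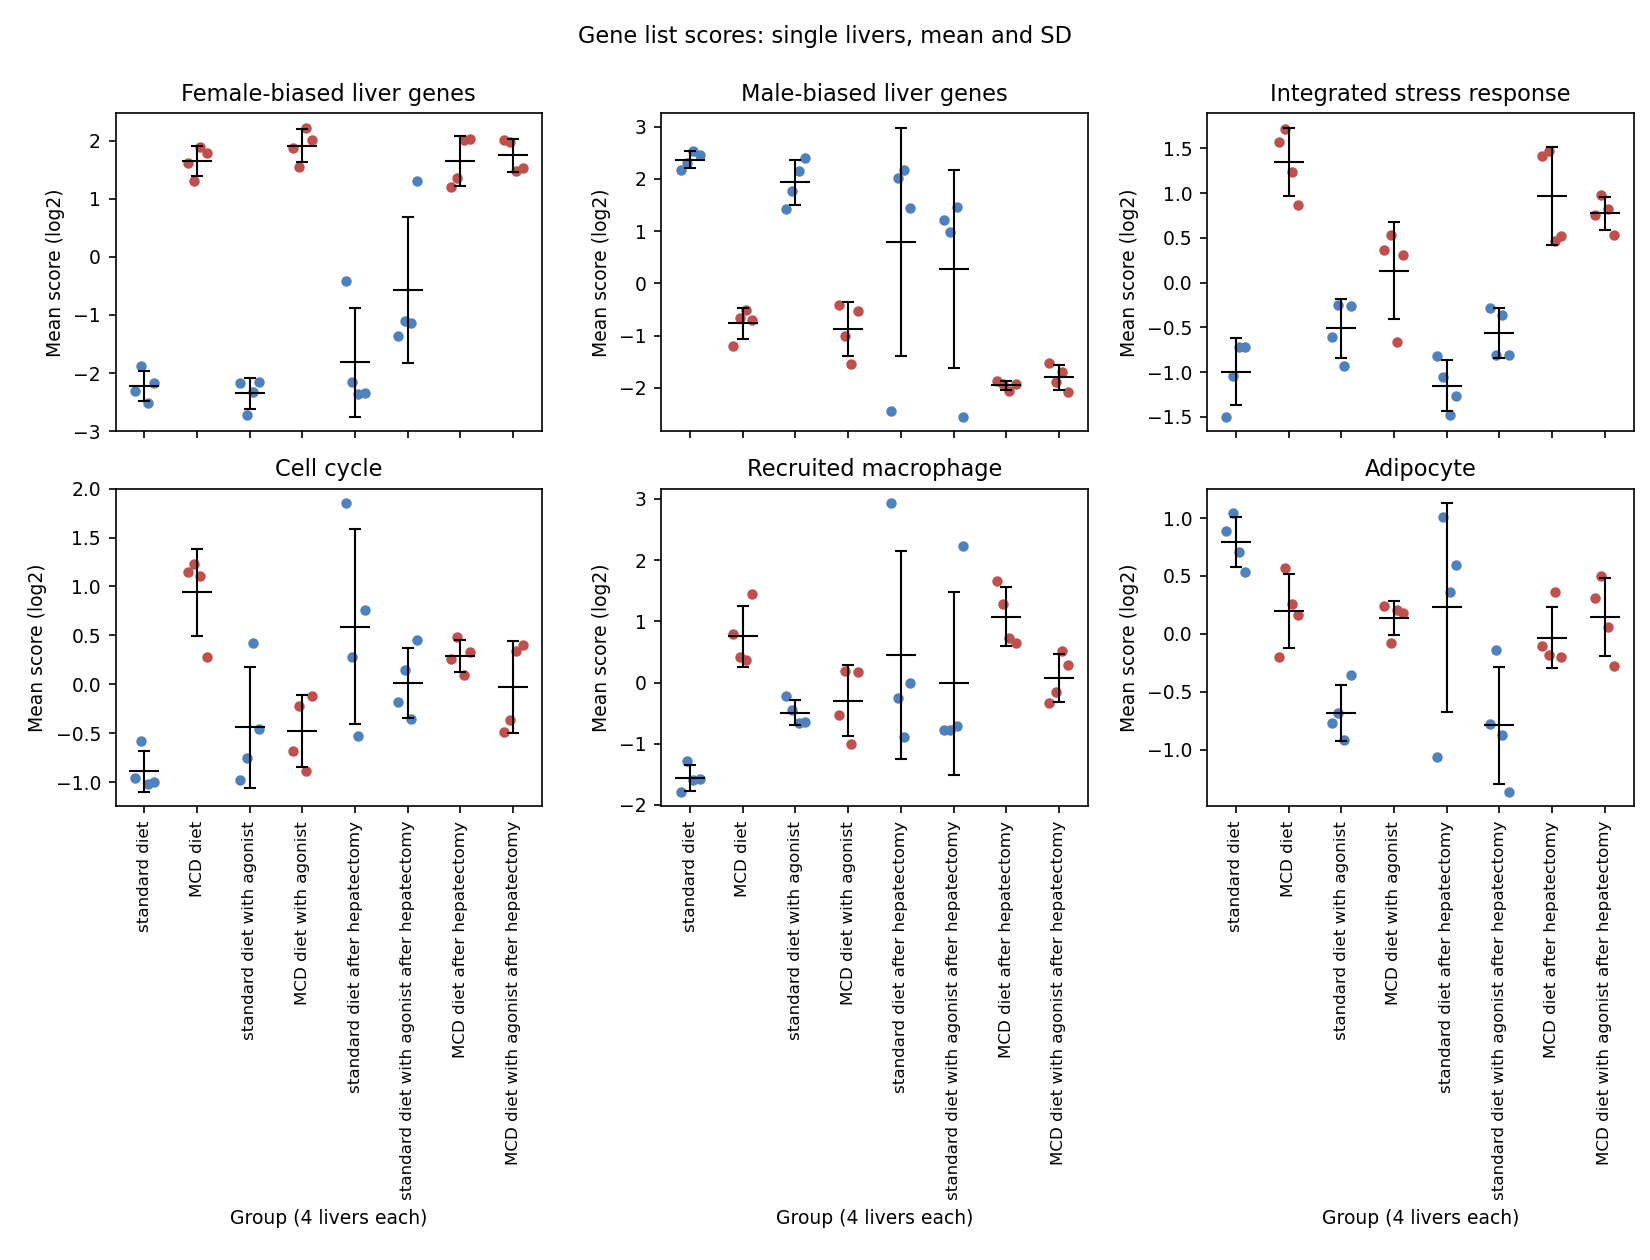
Mean log2 score of 6 gene lists on each of the 32 arrays, by group, as points for single livers with the group mean ± SD (n = 4). The recruited macrophage scores of standard diet after hepatectomy replicate 1 (2.94) and standard diet with agonist after hepatectomy replicate 4 (2.23) lie above the rest of their groups.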

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

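All tests in this part other than the diet by agonist interactions were chosen after the result they bear on was seen; for the recount without the 2 arrays that stand apart, the arrays were picked from the data but the bound was set before that count was known.

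Samples were screened for values far from the other 3 of their group (Dixon's test), over 328 combinations of group and measure. It picked 25, where chance gives about 16.4. Standard diet with agonist after hepatectomy replicate 4 was picked 6 times, with scores of -0.99 (others 0.51 to 0.61) for lipogenesis, 1.88 (others -0.3 to -0.04) for cytokines, -2.55 (others 0.98 to 1.46) for male-biased genes, 1.31 (others -1.37 to -1.1) for female-biased genes, 2.23 (others -0.78 to -0.72) for recruited macrophages and -0.46 (others 0.18 to 0.28) for T, NK and B cells. Standard diet after hepatectomy replicate 1 was picked 3 times, with -2.44 (others 1.45 to 2.16) for male-biased genes, -0.42 (others -2.36 to -2.15) for female-biased genes and -1.65 (others 0.16 to 0.39) for pericentral markers. MCD diet with agonist replicate 3 was picked 5 times, with -0.54 (others -0.07 to -0.01) for the p53 response, -0.79 (others -0.14 to -0.07) for ER chaperones, 0.87 (others -0.21 to -0.08) for periportal markers, -0.04 (others -0.85 to -0.82) for neutrophils and -0.5 (others 0.19 to 0.31) for erythroid cells.

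The remaining picks were spread over other arrays. MCD diet replicate 2 had -0.5 (others 0.06 to 0.16) for T, NK and B cells and -1.53 (others 0.16 to 0.34) for neutrophils, and MCD diet replicate 4 had 0.28 (others 1.11 to 1.23) for the cell cycle. Standard diet replicate 2 had a median net signal of 100.1 (others 59.61 to 63.74) and a cell cycle score of -0.58 (others -1.02 to -0.96). With agonist on standard diet, replicate 3 had -0.81 (others -0.07 to -0.02) for stellate cells and replicate 4 had -0.14 (others -0.59 to -0.54) for NRF2 targets. After hepatectomy, MCD diet with agonist replicate 1 had 49.84 (others 57.76 to 58.3) percent of probes well above background and 0.2 (others -0.16 to -0.11) for the respiratory chain, replicate 4 had -1.41 (others -0.15 to 0.01) for cholesterol synthesis, and MCD diet replicate 3 had 0.36 (others -0.2 to -0.11) for adipocytes. Differences between groups were tested as interactions, with 2406 genes for diet by agonist at baseline and 1 after hepatectomy. The agonist effect after minus before hepatectomy, in which a slide difference does not cancel, differed for 60 genes on standard and 242 on MCD diet.

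In the deposited processed table, 16 of 32 columns resemble arrays of another group. A changed normalization was argued against, because all 16 correlate better with an array of another group by more than 0.05 (smallest gain 0.0568). An exchange of columns in that table would give each a near-perfect match elsewhere, and the lowest such rank correlation was 0.9951, so a candidate explanation is that columns were exchanged there. Labels exchanged among the scanner files cannot be told apart from this: 32 of 32 scanner files carry their own sample's abbreviation, but names and labels come from the same hands. If the scanner labels were wrong instead, the MCD diet and standard diet with agonist groups would change places, which leaves only hepatectomy on standard diet and the diet by agonist interactions as they are.

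The 2 arrays on standard diet after hepatectomy that stand apart lie at 0.824 and 0.76 on the axis from standard to MCD diet, while the rest of their groups lie between 0.211 and 0.408. Low array quality was argued against, since 0 of the 2 lay outside the range of the other 30 arrays in probes above background or net signal. An exchange needs an MCD diet array out of place, but the lowest after hepatectomy lies at 0.784. Cyp2b9 (-4.397 and -2.082) lay at least 2.58 (log2) below all 16 MCD diet arrays. Sult1e1 (4.176 and 6.815) and Cyp4a12a (0.60 and 0.78) lay among them, so MCD livers under a wrong label stay open. A lower share of hepatocytes is argued against only if it raises all other cells alike. Macrophage markers rose beyond endothelial markers by at least 3.16 (log2). Recruited macrophages lay at 3.32 and 2.99, endothelial cells at 0.105 and -0.164 and cholangiocytes at 1.26 and 1.4 above the rest of the group. Inflamed or poorly regrown livers in these 2 animals stay open too.

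Many genes differed with the agonist at baseline and few after hepatectomy. An additive slide difference cannot be the whole cause at baseline, because the interaction that cancels it called 2406 genes, and the 2 agonist effects had r = -0.0653 with 149 of 221 shared calls in opposite directions (93.25 for independent lists). Without both arrays that stand apart 2 genes were called, but fewer livers cannot exclude a hidden response. Another hour of tissue collection would move clock genes on both diets only if all agonist livers shared it. Hlf, the 1 called on both, moved in opposite directions (-1.514 and 0.9458). On standard diet, where Nr1d1, Dbp and Arntl moved, time of day stays open. So do slide effects that differ between groups, longer treatment and a biological loss of response after hepatectomy, which only new samples may set apart. Time of day was not tested for the diet with agonist at baseline, the diet after hepatectomy and hepatectomy on standard diet, where the clock list was also called.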

How the results depend on the processing

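The values without the arrays that stand apart or carry acinar transcripts, and those with table columns placed at matching arrays, were chosen after seeing the data; all others were set before. Leaving out each array in turn gave between 4484 and 5408 called genes for the diet at baseline, 2570 to 3321 for the diet with agonist, 494 to 1482 for the agonist on standard diet, 1470 to 3159 on MCD diet and 1781 to 2704 for their interaction. After hepatectomy it gave 1 to 7 for the agonist on standard diet, 17 to 290 on MCD diet, 0 to 4 for the interaction and 1488 to 2934 for the diet, and hepatectomy called 1562 to 2978 on standard and 1389 to 1732 on MCD diet. The correlation of diet responses ranged over 0.313 to 0.408, that of agonist responses after hepatectomy over 0.0724 to 0.308, and before against after over -0.093 to 0.144 on standard and 0.242 to 0.332 on MCD diet, and 270 to 296 named genes stayed called.

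As labelled, the deposited table of processed values gave 1909 for the diet at baseline, with 60 named genes called. The agonist had 4754 and 2552 on standard diet before and after hepatectomy and 1520 on MCD diet after it. The interaction and the diet after hepatectomy had 0. The r was 0.0941 for the 2 diet responses and 0.714 for the agonist responses after hepatectomy. Before against after it was 0.509 on standard and 0.558 on MCD diet. As 16 columns of the table match another group, all but the interaction may stand for other contrasts. With columns placed at the matching arrays that table gave 2150 for the diet with agonist. After hepatectomy it gave 0 and 190 for the agonist on standard and MCD diet and 0 for the interaction. With normexp background correction r was -0.0238 for the agonist responses on MCD diet before and after. After hepatectomy the values were 0 and 165 for the agonist on standard and MCD diet and 0 for the interaction. The others were 1916 for the diet with agonist, 6846 for the agonist on MCD diet and 4627 and 1286 for hepatectomy on standard and MCD diet. Without the filter on dim probes the agonist had 812 on standard and 5404 on MCD diet. After hepatectomy it had 1 and 22, and the interaction 0. The r was 0.206 for the 2 diet responses and -0.00129 for the agonist responses on MCD diet before and after. After hepatectomy, quantile normalization, the mean over probes and outlier spots kept each gave 1 for the agonist on standard diet. Quantile normalization and median scaling each gave 0 for the interaction after hepatectomy. Fits to the compared groups alone gave 1248 for the diet with agonist, 267 for the agonist on standard diet, 1557 for the diet after hepatectomy and 1061 for hepatectomy on standard diet. Without the 2 arrays that stand apart there were 5 for the interaction after hepatectomy and 1682 for hepatectomy on standard diet. Without the 2 arrays with acinar transcripts there were 0 for the interaction after hepatectomy and r of 0.185 for the agonist responses on MCD diet before and after. With an estimated correlation there were 11 called lists. Outside the deposited table, the cause of moved values was not tested, but fits to the compared groups and those with arrays left out rest on fewer arrays. Genes not well above background on any array of a group have only a bound there, so signal over background limits which sizes can be given.

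Of 296 named gene calls, 11 were lost with median scaling, 10 with quantile normalization, 46 with normexp, 27 without the filter, 6 with the mean over probes, 2 with outlier spots kept and 49 in fits to the compared groups, and none changed direction. Over 2600 values of 300 printed gene results, 4 of which had not passed, leaving out single arrays lost 244 calls and gained 3. Of 142 list calls, 10 were lost with median scaling, 16 with quantile normalization, 21 with normexp, 11 without the filter and 11 in fits to the compared groups, and none reversed. The processed table was set beforehand for all results, but it was not run for the hepatectomy contrasts. For genes and lists it was run only for the number called.

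Replicate numbers do not pair the samples: 0 of 28 pairs of groups had every same-numbered pair of arrays over r = 0.1, and 17 of 112 such pairs did (r -0.207 to 0.444, median 0.0167). With the replicate block the agonist on MCD diet after hepatectomy called 100 genes and the interaction after hepatectomy 0, the block lost 6 of 296 named gene calls and 5 of 142 list calls, and no other count moved by more than 1.5 times.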

Other observations

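Of the tests here, the change of the agonist effect with hepatectomy was chosen after the result was seen; the regrouping tests were set after the counts but before any split was run.

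Hepatectomy on MCD diet also called the acinar list (camera adjusted p = 0.00938, adjusted p = 0.479 with an estimated correlation), 2 of 9 measured markers rising. Lists that passed in none of the 11 comparisons were VLDL assembly and export (lowest camera adjusted p = 0.407), gluconeogenesis (0.191), periportal hepatocytes (0.136), cholangiocytes (0.112) and mesothelial cells (0.211).

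The agonist effect after minus before hepatectomy differed for 60 genes on standard diet (34 up, 26 down) and 242 on MCD diet (63 up, 179 down). Unadjusted p was under 0.05 for 2723 and 3605. The effect before hepatectomy runs across slides, so a slide difference does not cancel in these counts. The Y-linked genes Ddx3y and Eif2s3y were well above background on 32 of 32 arrays and the 2 Xist probes on 0 and 1, as in male livers.

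Regrouping the 8 arrays of each pair of groups gives 35 splits, and 100 were drawn for the interactions. Chance is unlikely for the diet at baseline (5641 genes, highest other split 172) and the diet with agonist (3293 and 448). The same holds for the agonist on standard diet (1414 and 325) and on MCD diet (2876 and 5) at baseline and their interaction (2406 and 890). It can also be excluded for the diet after hepatectomy (2501 and 1154) and for hepatectomy on standard (2986 and 136) and MCD diet (2051 and 7); in each of these, 1 split, the real one, reached the count. The highest other split for the diet after hepatectomy put standard diet replicate 1 among the MCD arrays. Chance cannot be excluded for the agonist after hepatectomy on standard diet (2 genes, highest other 40, 8 of 35 splits as large), on MCD diet (88 and 150, 2 of 35) or for their interaction (1 and 67, 20 of 100). Why some splits called 40 and 67 genes was not tested.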
